A study of Homo sapiens with 6 samples.

How the data were processed

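Human lymphocyte RNA was analysed on 6 Affymetrix arrays, 1 per sample. Per the labels, the RNA was that of lymphocytes from blood, and how these were separated is not given in the sources used here. The samples were controls at 0 Gy or were exposed to 5 Gy of γ rays, with 3 samples per group. The series text speaks of doses between 0 and 5 Gy, and doses in between were not analysed here. Per the submitters' processing notes, the values were made with Affymetrix Expression Console and the robust multi-array average method, whose versions and settings are not given in the sources used here. The deposited values are on the log2 scale, already normalized between arrays, and are rounded to at most 2 decimals. Array signals near background are compressed by this method, so differences of weakly expressed genes are understated. The arrays' medians lay between 4.71 and 4.78, and the number of arrays limits the precision. The table held 0 columns of no sample.

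Of 54675 probe sets, 41097 had 1 gene symbol in the platform annotation, 1801 had several and 11777 had none. The Entrez identifiers of 41043 were found in the RefSeq gene table of GRCh38.p14, which was used for names only, and 0 symbols were updated. No coordinates are given, since the build of the array annotation is not given in the sources used here. Y-linked genes, XIST and TSIX (59 probe sets) and 6 control probe sets were left out. The remaining 41032 probe sets represent 19740 genes, each through its probe set with the highest mean over the 6 arrays, and 10511 genes had more than 1 probe set. Of the index genes and list members fixed in advance, some had no named probe set here and are not reported.

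The design, the naming rule, 22 gene lists and the first set of alternatives were chosen before the data were examined. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) without a block, with Benjamini-Hochberg adjustment over 19740 genes and a threshold of 0.05. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with adjustment over the 22 lists, and fry was the second test. Camera was repeated with the correlation estimated per list. In that setting camera also refers its statistic to the residual degrees of freedom of the fit. These are few with this number of arrays and fewer still with the block. A call lost in that setting thus does not by itself point to correlation between genes. The 22 lists were p53 targets, nucleotide and base excision repair, double-strand break repair and damage signalling, proliferation, replication-dependent histones, apoptosis regulators, interferon-stimulated genes, inflammatory and NF-κB targets, immediate early and stress genes, NRF2 and oxidative stress, cytosolic ribosomal proteins, oxidative phosphorylation, and markers of B cells, plasma cells, T cells, naive T cells, NK and cytotoxic cells, monocytes, neutrophils, platelets, erythroid cells and dendritic cells. Some genes stand in more than 1 list.

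Pairing was checked through the correlation, across genes, of the arrays' deviations from their group means. Arrays with the same number correlated at 0.771, 0.567 and 0.758, and arrays with different numbers at no more than 0.00497. The replicate numbers come from the sample titles. By the rule set for this check the numbers pair the samples, so the fit with replicate number as a block is given beside the fit without it. SDs beside log2 changes are over the 3 within-pair differences.

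The genes named were, by rule, the 12 with the largest increase and the 12 with the largest decrease among those past the threshold whose groups did not overlap. Where fewer passed, those of smallest p were named up to 5 per direction, as not past the threshold. To these were added 11 measured radiation index genes and up to 4 members of each list with the smallest p. The rule was applied to the fit without the block and repeated on the fit with it. It took 144 distinct genes, of which the text gives a part. PLK2, given with the p53 list, was named by the first part of the rule in the fit with the block.

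The fits were tested on simulated data for 19740 genes with 200 genes changed. The simulated arrays carried the replicate differences of the blocked fit and independent Gaussian noise at its moderated variances. They were thus built to favour the blocked fit, and the shares recovered do not measure its performance on the real arrays. Without the block, 0% of 67 genes changed by 0.5 on the log2 scale were recovered, 5.97% of 67 changed by 1 and 78.8% of 66 changed by 2. With the block, 29.9%, 100% and 100% were recovered, and 0.0102% of unchanged genes were called. Alternatives were the replicate block, centring on array medians, repeated quantile normalization, filters at the 30th percentile and at the median of level, the mean of a gene's probe sets, eBayes with trend and robust settings, array weights, an ordinary linear model, an estimated correlation in camera, and each array left out in turn. The same alternatives within the blocked fit, with both arrays of a replicate number left out in turn, were added after seeing the data. No batch or scan date is given in the sources used here, so none was tested.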

Results

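Gene expression was measured in human lymphocyte samples on 6 oligonucleotide arrays, 3 from unirradiated controls at 0 Gy and 3 from cells exposed to 5 Gy of γ rays, all 24 h after exposure. Each group carried the replicate numbers 1 to 3. The comparison asked how expression across the genome differed 24 h after 5 Gy. The 6 arrays had median log2 values between 4.71 and 4.78, and the number of arrays limits the precision. In total 19740 genes were tested. Replicate number took 76.6% of the sum of squares across genes, dose took 10.8% and the remainder was 12.6%. Arrays with the same number deviated together from their group means, so values from a fit with replicate number as a block stand beside those of the fit without it. The labels call the samples lymphocytes and do not say how these were separated from blood. FCGR3B, a neutrophil marker, stood at the 99.6th percentile of gene levels, the platelet marker PPBP at the 99.5th and the T cell marker CD3D at the 97.5th, so values of marker lists describe RNA preparations that held transcripts of several blood cell types. The labels do not say whether equal numbers mark equal donors. The p-values of single genes describe only these samples and rest on variances that eBayes moderates across all genes tested. Camera p-values at the preset correlation rest mainly on the spread across genes, so very small ones do not measure certainty over samples.

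After 5 Gy, 20 of 42 measured target genes of the tumour suppressor p53 rose in the fit with the replicate block, while 6 of 26 marker genes of NK and cytotoxic cells and 5 of 30 marker genes of B cells fell, and 0 of these passed without the block. By camera at its preset correlation of 0.01, all 3 lists passed in both fits. With an estimated correlation, the shift of the p53 list held without the block (adjusted p = 0.00722) and was lost with it (adjusted p = 0.229). The shifts of the NK and cytotoxic list (adjusted p = 0.159 without the block and 0.229 with it) and of the B cell list (adjusted p = 0.27 and 0.311) were lost in both fits. That setting also rests on the few residual degrees of freedom of the fit, so these losses cannot be ascribed to correlation between genes alone. The steepest increases with the replicate block were those of PCNA, the sliding clamp of DNA replication and repair, by 2.58 ± 0.41 on the log2 scale (mean ± SD of 3 pairs), and of TNFSF4, which encodes the OX40 ligand, by 2.47 ± 0.19. The steepest decrease was that of GZMA, which encodes granzyme A, at -1.52 ± 0.15. With limma and no block, 0 of 19740 genes passed an adjusted p of 0.05, the smallest adjusted p was 0.111, and 260 genes had an unadjusted p under 0.05. With the replicate block, 127 genes passed, 84 higher and 43 lower, and 1774 genes had an unadjusted p under 0.05. Of the 127 genes, 51 differed at least 2-fold, and all 127 differed in the same direction in all 3 pairs. Genes were called for differences large beside their moderated spread over pairs, so the shared direction is no separate support. The groups did not overlap for 44 of the 84 higher genes and 14 of the 43 lower genes. Over all genes tested they did not overlap for 4.87%. Chance gives 10% for arrays that can be exchanged freely, which these were not, and exchanging dose labels within 1 or 2 pairs gave 4.24% to 5.19%. Without both arrays of replicate 1, 2 or 3, the blocked fit called 4, 5 and 0 genes. PCNA, TNFSF4, TRIAP1 and ZMAT3 were called without replicate 1, and these 4 genes and ACER2 without replicate 2. The blocked count was 218 with array weights and 3 with an ordinary linear model, which does not moderate variances across genes. Of those 3 genes, 0 were among the 127.

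**Figure D1:**
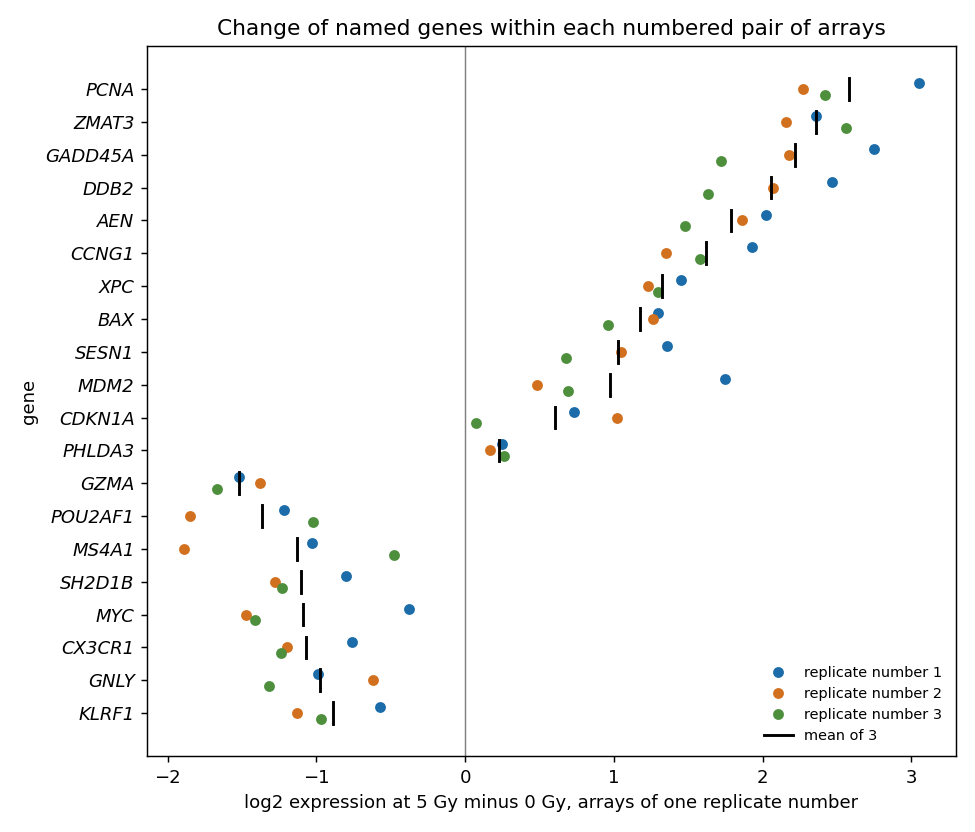
Log2 expression at 5 Gy minus 0 Gy (horizontal axis) for 20 named genes (vertical axis), with a point for each of the 3 replicate numbers and a bar at their mean. All 3 points lie above 0 for the p53 target genes, from PHLDA3 (mean 0.23) to PCNA (mean 2.58), and below 0 for the genes from GZMA (mean -1.52) to KLRF1 (mean -0.89).

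The list of p53 target genes had 42 measured members, of which 40 had a higher mean after 5 Gy and 31 were higher in all 3 pairs. Their median log2 change was 0.83, with pair medians of 1.24, 0.62 and 0.65 for replicates 1, 2 and 3. With the block, 20 members rose, 0 fell and 22 did not pass. Without it 0 passed over all genes, while 23 were higher when adjusted over the list alone, against 28 with the block. ZMAT3, an RNA-binding zinc finger protein, rose by 2.36 ± 0.20 (adjusted p = 1.25e-05 with the block). TRIAP1, an inhibitor of apoptosis, rose by 2.21 ± 0.12 and ASCC3, a helicase subunit, by 2.19 ± 0.55. GADD45A, a stress-inducible growth arrest gene, rose by 2.22 ± 0.52 and PLK2, a polo-like kinase, by 1.70 ± 0.37. The list stood above the other genes in camera (adjusted p = 2.39e-52 without the block), and the call held with an estimated correlation (adjusted p = 0.00722). With the block the call was lost with an estimated correlation (adjusted p = 0.229). The fry test gave an adjusted p of 0.00362 without the block and 0.0819 with it, and no other list passed it in either fit. In the same arrays the NK and cytotoxic marker list had a median of -0.50 and the B cell marker list a median of -0.33.

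Of the 11 radiation index genes measured, 8 rose with the block and 3 did not pass. All 11 also stand in the p53 list, so these 8 are among its 20 members that rose and add no separate support. DDB2, a damage-recognition factor of nucleotide excision repair, rose by 2.06 ± 0.42 (adjusted p = 0.000118 with the block). AEN, an apoptosis-enhancing nuclease, rose by 1.79 ± 0.28 and CCNG1, which encodes cyclin G1, by 1.62 ± 0.29. XPC, another recognition factor of nucleotide excision repair, rose by 1.33 ± 0.11, the pro-apoptotic BAX by 1.17 ± 0.19 and the sestrin gene SESN1 by 1.03 ± 0.34. MDM2, the ubiquitin ligase of p53, differed by 0.97 with pair values of 1.75, 0.48 and 0.69 and did not pass (adjusted p = 0.0702 with the block). CDKN1A, which encodes the cell cycle inhibitor p21, differed by 0.61 with pair values of 0.73, 1.02 and 0.07 (adjusted p = 0.225 with the block). PHLDA3 differed by 0.23 (adjusted p = 0.696 with the block). The 10 probe sets of MDM2 ranged from -0.18 to 0.97.

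Genes outside the p53 list also rose with the block. The list is a fixed selection, and whether these genes are p53 targets too was not tested. The 12 steepest increases with groups apart included ASTN2 at 2.25 ± 0.44, MCC at 1.86 ± 0.32 and ACER2, an alkaline ceramidase, at 1.76 ± 0.38. The probe sets of ASTN2 disagreed, from 0.01 to 2.25, and so did those of MCC, from 0.31 to 1.86. Without the block, the 5 genes of smallest p in the upward direction were ZMAT3, ACER2, CCNG1, ASCC3 and FBXO22, none past the threshold (adjusted p 0.111 to 0.115). FBXO22, an F-box protein gene of the p53 list, had a blocked adjusted p of 0.000275, and its 5 probe sets ranged from 0.11 to 2.00.

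Among 28 nucleotide and base excision repair genes, DDB2 and XPC, which also stand in the p53 list, rose with the block and 26 did not pass. The list had a median of -0.06 and a mean of 0.10, which differ in sign, and an adjusted camera p of 0.666 without the block. None of 29 genes of double-strand break repair and damage signalling passed in either fit (camera adjusted p = 0.469). PALB2, a partner of BRCA2, differed by 0.67 (adjusted p = 0.0692 with the block). Of 36 apoptosis regulators, 2 rose with the block, BAX and the death receptor gene FAS, the latter by 0.90 ± 0.51 (adjusted p = 0.0487), with 5 probe sets between 0.14 and 1.21. Both genes also stand in the p53 list. The apoptosis list had a median of 0.04, with an adjusted camera p of 0.191 without the block and 0.0297 with it, which was lost with an estimated correlation (adjusted p = 0.364).

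None of 44 proliferation genes passed in either fit. Their median change was -0.01, their median level 4.51 log2 units, and the adjusted camera p was 0.669. TYMS, thymidylate synthase, differed by 0.44 and MCM7, a subunit of the replicative helicase, by -0.36, neither past the threshold. The 31 replication-dependent histone genes had a median of 0.08 at a median level of 4.91, with 23 members higher and 0 past the threshold. Their list was called upward by camera (adjusted p = 0.00997), and this was lost with an estimated correlation (adjusted p = 0.629). It was also lost without control replicates 1 (adjusted p = 0.151) or 2 (0.138) and without irradiated replicates 2 (0.0752) or 3 (0.326).

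The NK and cytotoxic cell marker list had 26 measured members, 23 with a lower mean after 5 Gy and 22 lower in all 3 pairs. Its median change was -0.50, with pair medians of -0.42, -0.35 and -0.62. With the block 6 members fell and 20 did not pass. Adjusted over the list alone, 2 were lower without the block and 18 with it. GZMA was at -1.52 ± 0.15 (adjusted p = 0.000204 with the block and 0.111 without). SH2D1B, an adaptor of NK cell receptors, was at -1.10 ± 0.26, the fractalkine receptor gene CX3CR1 at -1.07 ± 0.27, the cytolytic granule gene GNLY at -0.98 ± 0.35 and the receptor gene KLRF1 at -0.89 ± 0.29. These 4 genes fell with the block. The probe sets of CX3CR1 ranged from -1.07 to -0.04 and those of SH2D1B from -1.10 to -0.52. The camera call (adjusted p = 2.91e-15 without the block) was lost with an estimated correlation (adjusted p = 0.159), and fry gave adjusted p = 0.247 without the block and 0.0819 with it. Marker genes of T cells had a median of -0.16 in the same arrays.

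B cell markers had 30 measured members, 28 with a lower mean after 5 Gy and 14 lower in all 3 pairs. The median was -0.33, with pair medians of -0.50, -0.58 and -0.15. With the block 5 members fell and 25 did not pass, and 15 were lower when adjusted over the list alone, against 0 without the block. POU2AF1, a B cell transcriptional coactivator, was at -1.36 ± 0.43 (adjusted p = 0.0023 with the block), and its other probe set was at -0.07. MS4A1, which encodes CD20, was at -1.13 ± 0.71, TCL1A at -1.06 ± 0.69, the immunoglobulin heavy chain gene IGHM at -1.03 ± 0.63 and CD72 at -0.77 ± 0.20. The 5 probe sets of IGHM, in a family of similar genes, ranged from -1.50 to -0.22. The camera call (adjusted p = 3.16e-11 without the block) was lost with an estimated correlation (adjusted p = 0.27), and fry gave adjusted p = 0.443 without the block and 0.226 with it. None of 13 plasma cell markers passed. Their median was -0.18, with an adjusted camera p of 0.087 without the block and 0.049 with it, and 0.364 with the block and an estimated correlation.

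None of 21 T cell markers passed in either fit. Their list had an adjusted camera p of 0.357 without the block and 0.0297 with it, downward, and this was lost with an estimated correlation (adjusted p = 0.442). Of 19 naive T cell markers, with a median of -0.04 and a camera adjusted p of 0.669, MYC fell with the block. MYC, a growth-promoting transcription factor gene, had pair values of -0.38, -1.47 and -1.41 (adjusted p = 0.031 with the block).

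Marker genes of other blood cells were measured in the same samples. The 24 monocyte markers had a median of -0.26 and pair medians of -0.17, -0.26 and -0.09. With the block 1 of them fell, CLEC7A, the receptor dectin-1, at -0.82 ± 0.13, with 6 probe sets between -0.82 and 0.00. The monocyte list call (adjusted p = 0.0107 without the block) was lost with an estimated correlation (adjusted p = 0.629), and without irradiated replicate 1 the list pointed upward (adjusted p = 0.952). The call was also lost without control replicates 2 (adjusted p = 0.209) or 3 (0.347). The 15 dendritic cell markers had a median of -0.02 and a mean of -0.21, and 3 fell with the block, TCF4 at -1.04 ± 0.42, IRF8 at -0.81 ± 0.27 and GZMB at -0.69 ± 0.16. TCF4 and IRF8 are transcription factor genes of dendritic and B cells, and GZMB encodes granzyme B and stands also in the NK list. The 8 probe sets of TCF4 ranged from -1.04 to -0.08. The dendritic list had an adjusted camera p of 0.0639 without the block and 0.0133 with it, and 0.348 with the block and an estimated correlation. The 26 neutrophil markers had a median of 0.06 (adjusted p = 0.666), and 1 of them rose with the block, CEACAM8, a granulocyte adhesion molecule gene, by 1.26 ± 0.21. The 18 platelet markers had a median of 0.11, with an adjusted camera p of 0.22 without the block and 0.00223 with it, upward, and 0.311 with the block and an estimated correlation. The 14 erythroid markers had a median of 0.05 (adjusted p = 0.087).

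**Figure D2:**
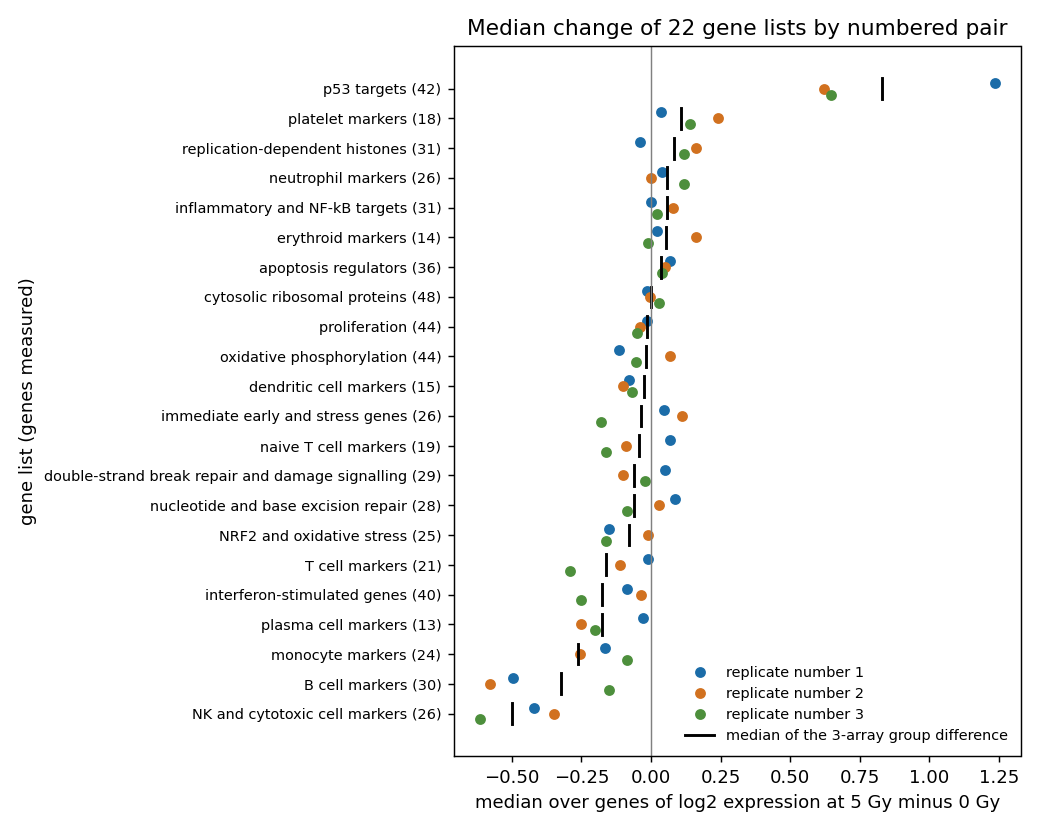
Median over genes of log2 expression at 5 Gy minus 0 Gy (horizontal axis) for 22 gene lists with the number of genes measured (vertical axis), with a point for each of the 3 replicate numbers and a bar for the median of the difference between group means. The p53 targets lie at 1.24, 0.62 and 0.65 and the NK and cytotoxic markers at -0.42, -0.35 and -0.62.

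The 40 interferon-stimulated genes had a median of -0.18, with 31 lower and 0 past the threshold. Their downward camera call (adjusted p = 0.0107 without the block) was lost with an estimated correlation (adjusted p = 0.27), and without control replicates 2 (0.121) or 3 (0.259) or irradiated replicate 1 (0.065). IFI44L differed by -0.64 and IFI6 by 0.50, neither past the threshold. Of 31 inflammatory and NF-κB target genes, TNFAIP6, a hyaluronan-binding protein gene, rose with the block by 0.69 ± 0.06, and the list had a camera adjusted p of 0.778. Of 26 immediate early and stress genes, MYC fell with the block, and EGR3 differed by 0.74 without passing (list adjusted p = 0.757). None of 25 NRF2 and oxidative stress genes (adjusted p = 0.469), 48 cytosolic ribosomal protein genes (adjusted p = 0.666) or 44 oxidative phosphorylation genes (adjusted p = 0.916) passed in either fit.

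The remaining genes named among the 12 steepest decreases with groups apart were TBC1D9 at -1.12 ± 0.29, RASGEF1A at -0.92 ± 0.10, LOC101929305 at -0.92 ± 0.39, RTP4 at -0.89 ± 0.48, HLA-DMB at -0.87 ± 0.33 and the chemokine gene XCL1 at -0.87 ± 0.38. HLA-DMB encodes a chain of the HLA-DM peptide exchange factor. Probe sets disagreed for TBC1D9 (-1.12 to -0.01), XCL1 (-0.87 to -0.04), LOC101929305 (-0.92 to -0.28) and RASGEF1A (-0.92 to -0.38). Without the block, the 5 genes of smallest p in the downward direction were GZMA, CX3CR1, FHOD1, IDH1 and TBC1D9, none past the threshold, and FHOD1 and IDH1 did not pass with the block either (adjusted p = 0.106 and 0.0733). An exact test of a single gene with 3 arrays against 3 cannot give a two-sided p below 0.1.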

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

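All tests of explanations in this part were chosen after the results were seen. Outside the named genes, 11721 probe sets with no gene symbol were tested in the same way. With the replicate block 2 of them passed, both higher after 5 Gy, and 0 were lower, while 0 passed without the block. They drew attention because they lie outside the comparison of named genes.

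Chance was examined by regrouping the arrays. For the fit without a block, all 10 splits of the 6 arrays into 3 and 3 gave as many genes as the real one, since the real split called 0 and the highest other split called 0. With a real count of 0 this outcome was fixed in advance, so it says nothing about chance. At an unadjusted p under 0.05 the real split gave 260 genes, and the split that put control replicates 1 and 2 with irradiated replicate 1 gave 3545, which points to the structure of the samples by replicate number. For the blocked fit, 4 patterns part all 3 pairs, and the real one called 127 genes while the highest of the other 3, which exchange dose labels within 1 or 2 pairs, called 0, so 1 of 4 gave as many. Both sets of regroupings are too few for a share under 0.05.

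With the block, 6 of 26 marker genes of NK and cytotoxic cells and 5 of 30 of B cells fell, and 0 passed without it. The lists' downward calls were lost with an estimated correlation (adjusted p = 0.159 and 0.27 without the block, 0.229 and 0.311 with it). A smaller lymphocyte share of the RNA would lower T cell markers as far. Against this as the whole explanation for the NK and cytotoxic list, the T cell median lay above the NK median in 3 of 3 pairs, by a mean of 0.325 with an SD of 0.085. The T cell medians were themselves at -0.01, -0.11 and -0.29, so a smaller share stays open as a part of the fall. For B cells, the T cell median less the B cell median averaged 0.272 with an SD of 0.357 and was -0.14 in replicate 3. A smaller lymphocyte share thus cannot be told apart from a change of B cells themselves, because the 3 pairs differ too much. Loss of NK or B cells and lower transcript levels per cell both stay open as effects of dose, and neither was tested.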

How the results depend on the processing

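The alternatives applied within the blocked fit, and the omission of both arrays of a replicate number, were chosen after seeing the data. Except where stated, the cause of a change was not tested. Values for lists are adjusted camera p. In the fit without a block, the count stayed at 0 genes with centring, repeated quantile normalization, both level filters, the mean of probe sets, trend and robust moderation and each array left out. The p53 list stayed past the threshold in every setting of that fit.

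Array weights gave 10 genes without a block, 9 higher and 1 lower, all 10 at least 2-fold. The ordinary linear model gave 1 gene, IQCF2, at -0.03, whose values were equal within each group after rounding. The replicate block gave 127 genes, 84 higher, 43 lower and 51 at least 2-fold. It also brought past the threshold apoptosis regulators (0.0297), T cell (0.0297), plasma cell (0.049), dendritic cell (0.0133) and platelet markers (0.00223), and changed the call of no other list. Dendritic cell markers passed with the filters at the 30th percentile (0.0109) and at the median (0.00327), with mean probe sets (0.0377) and with array weights (0.00996). Apoptosis regulators passed with the median filter (0.0303) and mean probe sets (0.0364), erythroid markers with mean probe sets (0.0213), and plasma cell (0.000166) and neutrophil markers (0.022) with array weights. With an estimated correlation the calls of histones (0.629), interferon-stimulated genes (0.27), B cell (0.27), NK and cytotoxic (0.159) and monocyte markers (0.629) were lost. Camera was not run with the ordinary linear model.

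Leaving out each array in turn, without a block, the adjusted p ranged from 0.0175 to 0.826 for excision repair, 9.38e-05 to 0.326 for histones, 0.0275 to 0.743 for apoptosis regulators, 0.000137 to 0.259 for interferon-stimulated genes, 0.00679 to 0.826 for inflammatory targets, 0.0134 to 0.826 for immediate early genes, 0.0314 to 0.952 for NRF2 genes and 0.0159 to 0.773 for ribosomal proteins. For markers it ranged from 0.00214 to 0.951 (plasma cells), 1.68e-05 to 0.708 (T cells), 0.000124 to 0.951 (naive T cells), 4.34e-07 to 0.952 (monocytes), 7.26e-05 to 0.535 (neutrophils), 7.14e-06 to 0.762 (platelets), 0.00607 to 0.474 (erythroid) and 0.0149 to 0.368 (dendritic cells). Among lists past the threshold with all arrays or without the array in question, the direction turned for monocyte markers without irradiated replicate 1 (0.952, upward), for inflammatory targets (0.0445), neutrophil (0.000159) and platelet markers (0.0458) without control replicate 1 (downward), for immediate early genes without control replicate 3 (0.0325, upward) and for naive T cell markers without irradiated replicate 3 (0.0309, upward). It also turned in 21 of the 132 combinations of list and array, over 13 lists, that passed in neither case, among them T cell markers without control replicate 1 (0.208) and without irradiated replicate 3 (0.0726). Histones lost their call without control replicates 1 (0.151) and 2 (0.138) and irradiated replicates 2 (0.0752) and 3 (0.326), each in turn. Interferon-stimulated genes lost theirs without control replicates 2 (0.121) and 3 (0.259) and irradiated replicate 1 (0.065), and monocyte markers without control replicates 2 (0.209) and 3 (0.347).

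Within the blocked fit, the count was 110 with centring, all 110 among the 127, and 125 with repeated quantile normalization, 120 of them shared. Mean probe sets gave 86 genes, 76 shared, with 20 lower. Array weights gave 218 genes with 98 lower, which include the 127. The ordinary linear model gave 3 genes, 0 higher and 3 lower, 0 at least 2-fold and 0 shared. They were IQCF2, LINC02029 and REEP5, named after their values were seen, whose 3 pair differences were equal after rounding. Without both arrays of a replicate number, which leaves 2 pairs, the ranges were 0 to 5 genes changed, 0 to 5 higher, 0 lower and 0 to 5 at least 2-fold.

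The blocked list calls changed as follows. Repeated quantile normalization moved apoptosis regulators and plasma cell markers to 0.0516 each. The 30th percentile filter moved plasma cell (0.107) and T cell markers (0.0569). The median filter moved histones (0.0531), plasma cell (0.207) and T cell markers (0.0726) and brought in inflammatory targets (0.0392). Mean probe sets moved T cell markers (0.0954) and brought in inflammatory targets (0.0237) and erythroid markers (0.0354). Trend and robust moderation moved plasma cell markers (0.054), and array weights moved apoptosis regulators and plasma cell markers (0.0575 each). With an estimated correlation all calls were lost, p53 targets (0.229), NK and cytotoxic (0.229), B cell (0.311), monocyte (0.311), platelet (0.311), dendritic cell (0.348), plasma cell (0.364) and T cell markers (0.442), histones (0.364), apoptosis regulators (0.364) and interferon-stimulated genes (0.364). The estimate lay below the preset of 0.01 for monocyte (-0.0327), dendritic cell (-0.00276) and platelet markers (0.0017). Correlation between genes thus does not account for the loss of these calls. The other lists that lost their call had estimates above the preset, such as 0.0271 for NK and cytotoxic and 0.188 for B cell markers. How far correlation and how far the few residual degrees of freedom account for these losses was not tested. Without both arrays of a replicate number the ranges were 0.00339 to 0.167 for histones, 0.0389 to 0.155 for apoptosis regulators and 0.0432 to 0.576 for inflammatory targets. For markers they were 0.0153 to 0.438 (plasma cells), 0.00294 to 0.369 (T cells), 0.0218 to 0.996 (naive T cells), 0.000959 to 0.0843 (monocytes), 0.00157 to 0.134 (platelets) and 0.0207 to 0.142 (dendritic cells). The proliferation, histone, erythroid and dendritic lists had the lowest median levels, 4.51, 4.91, 5.05 and 5.06, and whether signal over background limits them was not tested.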

Other observations

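Of the 84 genes that rose with the replicate block, 62 were in none of the 22 lists, and of the 43 that fell 28 were in none. The lists are fixed selections, so a gene in none of them can still belong to a group that a list stands for. The genes named in this paragraph were chosen after their values were seen. Besides TNFSF4, the TNF family ligand gene CD70 rose by 0.76 ± 0.10 (mean ± SD of 3 pairs) and the receptor gene TNFRSF9, which encodes 4-1BB, by 0.71 ± 0.08, while the ligand gene TNFSF13, which encodes APRIL, was at -0.77 ± 0.28. The probe sets of TNFRSF9 ranged from -0.01 to 0.71. MPEG1, the perforin-2 gene of phagocytes and B cells, was at -1.40 and the chemokine receptor gene CCR2 at -0.79, while its other probe set was at 0.03. Over-representation among the 127 genes was tested for the 22 lists with Fisher's exact test. The p53 list held 20 of them where 0.27 were expected (adjusted p = 3.1e-32), the NK and cytotoxic list 6 (adjusted p = 1.43e-07), the B cell list 5 (adjusted p = 9.36e-06) and the dendritic list 3 (adjusted p = 0.000615). This test treats genes as independent. In the blocked fit camera with an estimated correlation gave adjusted p of 0.229, 0.229, 0.311 and 0.348 for these 4 lists. Those values rest also on the few residual degrees of freedom of the fit, so they do not single out dependence between genes. For the dendritic list the estimated correlation was -0.00276.

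The following tests were chosen after members of each group had been seen among the called genes. The TNF and TNF receptor family may shift as a group, but its 43 measured genes outside the p53 list gave a camera p of 0.127 with the block and a median of 0.02, which leaves this open. HLA class II genes other than HLA-DMB may shift downward together. Their 13 measured genes had a median of -0.31 and pair medians of -0.51, -0.23 and -0.37, and camera with the block gave p = 8.09e-06 at the preset correlation and p = 0.0695 with an estimated correlation, so the test leaves this open too.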
